A study of Homo sapiens with 8 samples.

How the data were processed

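RNA abundance was measured in HL60 cells, a human acute promyelocytic leukaemia line, after 72 h with phosphate-buffered saline (PBS), VC (vitamin C, as the series title spells it out), DZNep (3-deazaneplanocin A, an inhibitor of S-adenosylhomocysteine hydrolase that lowers the histone methyltransferase EZH2) or VC with DZNep. Each of the 4 groups had 2 libraries, 8 in all, prepared from total RNA with an Illumina TruSeq kit. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p values measure the spread between these libraries, whatever its source. The table calls the drug-free columns control, and these were taken as the PBS group, which is the only drug-free group in the labels.

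The submitters' processing notes name HISAT2 2.0.4, SAMtools 1.3.1, HTSeq 0.6.0 and DESeq 1.18.1 with builds hg38 and GRCh38, and the table's own sheet name adds EDASeq. The deposited values are therefore treated as a score, a normalized whole number per gene and library, and not as read counts. This was checked on the values: all 8 libraries hold the same sorted values, with a total of 1988507, a median of 88, a lowest value of 2 and a highest of 10345. In each library 10 genes share the highest value, and exactly 1 of them falls in each decile of genes by genomic span, in 80 of 80 combinations of decile and library. Deciles by GC content gave this in 26 combinations and deciles by exon length in 32. The values thus behave as ranks within deciles of gene span that were mapped onto 1 common distribution. The settings of that step, the annotation and the filter on genes are not stated.

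Several limits follow for the measurements. The read depth of each library is unknown, and no counting interval is given. A shift shared by most genes would have been removed. Values of different genes are not comparable as abundances. Steps between neighbouring values are large at the low end, with a median of 0.22 and a largest step of 1.00 on the log2 scale among values from 2 to 10. Above 2000 the median step is 0.0013 and the largest 0.54, and between 50 and 200 they are 0.0122 and 0.04.

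The table holds 9543 genes, all matched by Ensembl identifier to protein-coding genes of GENCODE 29, which supplied coordinates on GRCh38, gene span, GC content and exon length. Genes with a mean value under 10 over the 8 libraries were dropped (30 genes), and 9513 were tested. Values were taken as log2(value + 1). With limma 3.58.1 in R 4.3.3, one mean per group was fitted to all 8 libraries, and moderated statistics were computed with an intensity trend in the prior variance (6.46 prior and 4 residual degrees of freedom). Tests were two-sided. There were 6 comparisons: each drug group against PBS, the combination against DZNep alone and against VC alone, and the interaction, which asks whether the VC effect differed with and without DZNep. P values were adjusted by Benjamini-Hochberg over genes within a comparison, with a threshold of 0.05. The expected number of unadjusted p values under 0.05 by chance is 476 per comparison. Errors of fold changes are limma standard errors (SE). Group values are means with SD over n = 2 libraries.

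The groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule took, for the comparisons against PBS and against DZNep, the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 50 in the higher group and both treated libraries beyond both reference libraries. For the combination against VC and the interaction it took 5 and 5. Where fewer than 3 genes passed, it took the 5 smallest p values. It added up to 4 members of each list with the smallest p, and a fixed set of genes tied to these drugs or to leukaemia cells, of which 3 were not analysed here.

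The 30 gene lists cover pathways, myeloid maturation, chromatin enzymes, the translation machinery and markers of other cell types. Each was tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the 30 lists within a comparison. The rotation test fry was run beside it. Camera compares a list with all other genes. Fry asks whether a list's genes move one way on balance. Members past the threshold were counted over all genes and adjusted over the list alone. Camera with an estimated correlation rests on the 4 residual degrees of freedom as well as on the correlation, so its p is much larger.

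The fit was tested on simulated data, in which the fitted spread was kept, known changes were put in and the values were mapped onto the deposited distribution. For DZNep against PBS, 35.8% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 95.5% of those changed 4-fold were called in the right direction. For VC against PBS these shares were 20% (13 of 65), 81.2% and 98.5%, and for the interaction 7.58%, 31.3% and 76.9%. The simulated VC effect changed 65, 64 and 65 genes by these folds and shifted a list. Calls of many changed genes relax the adjusted threshold. The shares may thus be too high where few genes pass, as in the measured VC against PBS, and they do not bound what was missed there. Of the unchanged genes, 6 of 9214 were called for DZNep against PBS, 8 of 9211 for the combination against DZNep and 2 of 9211 for the interaction. The measured data gave 64 and 2 calls in the latter 2 comparisons. The false calls arose beside those of planted changes, with noise drawn separately for each gene, so they set no noise floor for the measured counts. A shifted list was recovered in each comparison, and 1 other list was called in the combination against VC.

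Agreement between 2 sets of fold changes was described across genes, which are not independent replicates. Where the comparisons shared libraries, 100 simulations of unchanged groups gave the value that sharing alone produces. Alternatives covered scaling, the filter, the pseudocount, the variance prior, observation weights, the libraries in the fit, a fold threshold, a replicate block and leaving out each library in turn. After seeing the data, a restriction to genes with a mean from 20 to 2000 and a removal of GC and exon-length trends were added. The count-based alternative was not run because the values are not counts.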

Results

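Expression of 9543 protein-coding genes was measured in 8 HL60 libraries, 2 each after 72 h of PBS, VC, DZNep or VC with DZNep. By its title, the series asks how vitamin C alters the anti-leukaemic action of DZNep. Each library totals 1988507 normalized units because the deposited values share 1 distribution, so depth per library is not known and precision rests on the spread between the 2 libraries of a group. Within groups, Spearman's rho across genes was 0.979 for PBS, 0.982 for DZNep, 0.987 for VC and 0.984 for the combination. Pairs of a PBS and a VC library had a rho of 0.982 to 0.984, so the PBS libraries were no closer to each other than to those with VC. The first principal component carried 50.4% of the variance and split the libraries with DZNep (15.7 to 26.2) from those without (-24.3 to -18.0), while the second carried 12.3%.

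**Figure D1:**
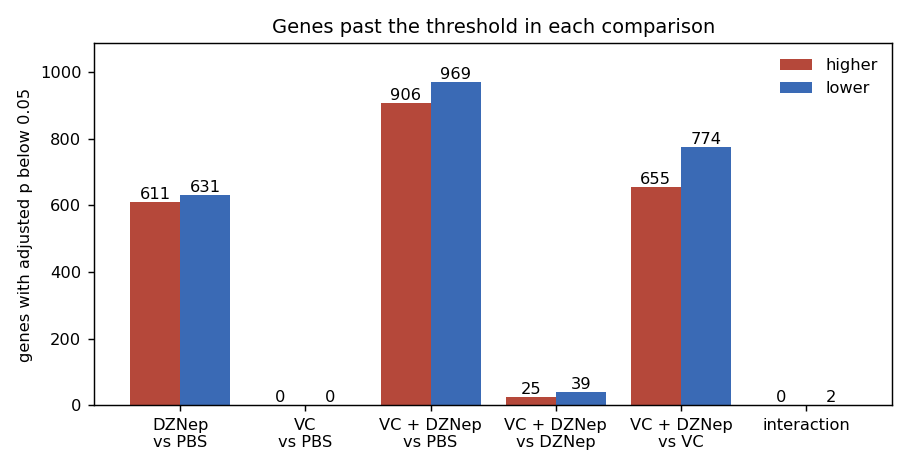
Numbers of genes with a limma adjusted p below 0.05 in each comparison, higher (red) and lower (blue) in the group named first. DZNep against PBS gave 611 and 631 genes, VC against PBS gave 0 and 0, and the combination against DZNep gave 25 and 39.

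The effect of DZNep alone was asked by comparing it with PBS. CLC (ENSG00000105205, chr19:39731250-39738028, minus strand), the Charcot-Leyden crystal protein of eosinophils and basophils, was 13.6-fold higher, at 374 ± 17.0 against 27 ± 7.07 units (SD, n = 2). SETD2 (ENSG00000181555, chr3:47016429-47163967, minus strand), the histone H3 lysine 36 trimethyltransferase, was 4.84-fold higher, at 1496 ± 74.2 against 308 ± 17.0 units. SRGN, the proteoglycan core protein of secretory granules, was 4.16-fold higher, and the centromere protein gene CENPF rose 3.19-fold. Decreases were led by CLEC7A, the beta-glucan receptor dectin-1, which dropped from 92.5 ± 28.99 to 13.5 ± 6.36 units, a 6.62-fold difference. IPO5 (ENSG00000065150, chr13:97953658-98024297, plus strand), a nuclear import receptor, was 4.68-fold lower, at 894 ± 33.9 against 4222 ± 811 units.

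In all, 1242 of 9513 genes (13.1%) passed the limma threshold, 611 higher and 631 lower, and 251 of them differed at least 2-fold. The log2 fold changes were 3.77 ± 0.301 (SE) for CLC with an adjusted p of 9.26e-05, 2.28 ± 0.0996 for SETD2 with 2.73e-06, and -2.23 ± 0.141 for IPO5 with 2.03e-05. The other large increases were the histone gene HIST1H4I (log2 fold change 2.00), the eosinophil ribonuclease gene RNASE2 (1.85), the actin-like gene ACTL8 (1.84), the extracellular matrix gene EMILIN2 (1.72), the calprotectin subunit gene S100A9 (1.64) and the prostaglandin dehydrogenase gene HPGD (1.60). Other large decreases included the nucleoside transporter gene SLC28A3 (-2.38), the glutathione-degrading enzyme gene CHAC1 (-2.36), the lysophosphatidic acid receptor gene LPAR2 (-2.32), ELFN2 (-2.23), the glucocorticoid-induced leucine zipper gene TSC22D3 (-1.92), the AP-1 gene JUN (-1.91) and the growth arrest gene GADD45A (-1.83). Without PBS replicate 1 or 2 the count was 730 or 792, without DZNep replicate 1 or 2 it was 538 or 439, and 739 genes passed without the intensity trend and 454 with the 4 libraries alone. The CHAC1 call was lost without PBS replicate 1 or 2 (limma adjusted p = 0.0766 and 0.0515) and without DZNep replicate 1 or 2 (0.115 and 0.0541), and that of HPGD without DZNep replicate 2 (0.0531), with alternatives reaching from 0.0013 to 0.115 and from 0.00101 to 0.055.

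The integrated stress response list, genes that the transcription factor ATF4 induces under amino-acid shortage and related stresses, had the smallest p of the 30 lists. Of its 35 measured genes, 29 fell over all genes tested and 32 fell adjusted over the list alone. Their median log2 fold change was -0.87 (camera adjusted p = 1.3e-23, and adjusted p = 0.00828 with an estimated correlation). The serine synthesis genes PSAT1 and PHGDH fell by 1.19 and 1.68 on the log2 scale, the asparagine synthetase gene ASNS by 1.06 and the tryptophanyl-tRNA synthetase gene WARS by 1.29. PSAT1 (ENSG00000135069, chr9:78297143-78330093, plus strand) went from 747 ± 7.07 to 328 ± 10.6 units.

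Of 38 DNA replication genes, 12 fell over all genes, and adjusted over the list alone 16 fell and 1 rose (median -0.43, camera adjusted p = 5.01e-07, and adjusted p = 0.0442 with an estimated correlation). They included the ribonucleotide reductase subunit gene RRM2 (-1.14), the sliding clamp gene PCNA (-0.87) and the licensing factor gene CDT1 (-0.71). The immediate early list, genes switched on within minutes of a signal, had 6 of 13 members lower, and 10 adjusted over the list alone (median -0.47, camera adjusted p = 2.96e-05, but adjusted p = 0.0843 with an estimated correlation). JUN led these decreases. Of 24 cholesterol synthesis genes 6 fell, and adjusted over the list alone 6 fell and 1 rose (median -0.28, camera adjusted p = 0.0193, but adjusted p = 0.252 with an estimated correlation). The call of the list was lost without PBS replicate 1 (camera adjusted p = 0.0613) and without DZNep replicate 1 (0.143), over alternatives from 0.00609 to 0.143.

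Among 14 measured genes of the list for the primary granule and the promyelocyte, 8 rose and 1 fell, and adjusted over the list alone 9 rose and 1 fell (median 0.48, camera adjusted p = 8.87e-06, but adjusted p = 0.0843 with an estimated correlation). Not all of its genes encode granule proteins. SRGN, the hepatocyte growth factor gene HGF (1.16), the serpin gene SERPINB10 (0.98) and the protein disulphide isomerase gene P4HB (0.81) rose, whereas MPO, the myeloperoxidase gene that marks this granule, was not called (0.21, limma adjusted p = 0.291). MPO passed without PBS replicate 1 (0.0346) and had an adjusted p of 1 without PBS replicate 2, over alternatives from 0.0346 to 1. Markers of other cell types moved beside this list. The megakaryocyte integrin gene ITGA2B, 1 of 2 erythroid and megakaryocyte genes measured, rose by 0.70 ± 0.112 (limma adjusted p = 0.00337, both libraries higher), from 412 ± 53.7 to 669 ± 69.3 units, and was called in all 22 alternatives. The 4 lymphoid genes were all positive, with 0 past the limma threshold over all genes and 1 higher adjusted over the list alone (median 0.83, camera adjusted p = 0.139, fry adjusted p = 0.0258).

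Of 8 histone genes 6 rose, and adjusted over the list alone 6 rose and 1 fell (median 1.39, camera adjusted p = 0.00245, but adjusted p = 0.285 with an estimated correlation), with HIST1H4I and HIST1H2BK (1.22) as examples. Of 40 ribosome biogenesis genes 7 rose and 2 fell, over all genes and adjusted over the list alone (median 0.24, camera adjusted p = 0.000853, but adjusted p = 0.225 with an estimated correlation). The nucleolar phosphoprotein gene NPM1 fell by 0.89, while UTP20 (1.07) and RRP1B (0.76), of the pre-ribosome, rose. Of 78 ribosomal protein genes 5 fell and 1 rose, over all genes and adjusted over the list alone (median -0.04, camera adjusted p = 0.0363, but adjusted p = 0.252 with an estimated correlation). That call was lost without PBS replicate 1 (camera adjusted p = 0.0956) and without DZNep replicate 2 (0.0733), over alternatives from 0.00386 to 0.0956.

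EZH2, the histone H3 lysine 27 methyltransferase gene (ENSG00000106462), was at 133 ± 38.2 units with DZNep and 222 ± 14.1 units with PBS (log2 fold change -0.76 ± 0.17, limma adjusted p = 0.0165). Its call was lost without PBS replicate 1 or 2 (limma adjusted p = 0.0533 and 0.0857) and without DZNep replicate 2 (0.093), over alternatives from 0.00484 to 0.0986. The maintenance DNA methyltransferase gene DNMT1 fell by 0.79 ± 0.109 (limma adjusted p = 0.00168). The antiapoptotic gene BCL2 was lower as well (-0.62 ± 0.166, limma adjusted p = 0.0346), a call lost without PBS replicate 1 or 2 (0.165 and 0.0609) and without DZNep replicate 1 or 2 (0.164 and 0.137), over alternatives from 0.0145 to 0.165. Proapoptotic genes of the same BCL2 family and caspase list fell too: BBC3 (-1.355, limma adjusted p = 0.0101), PMAIP1 (-1.09, 0.00432), BMF (-0.86, 0.00319) and TNFRSF10B (-0.45, 0.0377). They were called in 19 of 21, 21 of 22, 22 of 22 and 15 of 22 alternatives, and 1 gene of the list rose. MYC (0.52, limma adjusted p = 0.00652) and MKI67 (0.38, 0.024) were higher, called in 20 of 22 and 17 of 21 alternatives. AHCY, which encodes the enzyme that DZNep inhibits, was not called (-0.01, limma adjusted p = 0.982), and neither were the dioxygenase gene TET2 (0.30, 0.195), the antiapoptotic gene MCL1 (0.00, adjusted p of 1) and the integrin gene ITGAM (-0.21, 0.549).

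VC alone was compared with PBS to ask what it did without DZNep. No gene passed the limma threshold, a count of 0, and 462 had an unadjusted p under 0.05. The smallest p belonged to TFRC (ENSG00000072274, chr3:196027183-196082189, minus strand), the transferrin receptor gene that brings iron into cells, at 781 ± 89.1 against 448 ± 21.9 units. Its log2 fold change was 0.80 ± 0.0996 and its limma adjusted p was 0.0839. The next smallest were the actin-severing gene CFL1 (0.64, adjusted p = 0.361), the secreted glycoprotein gene CHI3L1 (0.71, 0.361), the heterochromatin protein gene CBX5 (-0.47, 0.954) and the phosphatase regulator gene PHACTR1 (0.69, 0.954), which did not pass. EZH2, DNMT1 and BCL2 gave -0.09, -0.26 and -0.57 with limma adjusted p of 0.989, 0.954 and 0.954. The count was 1 under median-of-ratios scaling and 1 without VC replicate 1. The adjusted p of TFRC ranged from 0.0201 to 0.877 over 22 alternatives and passed in 3.

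Among the gene lists, the NRF2 antioxidant list, genes of glutathione, thioredoxin and NADPH metabolism, was shifted up with VC alone. Of its 24 genes 20 were positive, with 0 past the limma threshold over all genes and 1 adjusted over the list alone (median 0.15, camera adjusted p = 1.38e-05, but adjusted p = 0.15 with an estimated correlation, fry adjusted p = 0.0106). The immediate early list was shifted down, with 12 of 13 genes negative and 0 past the threshold either over all genes or adjusted over the list alone (median -0.18, camera adjusted p = 0.0444, but adjusted p = 0.326 with an estimated correlation). That call was lost without PBS replicate 1 (camera adjusted p = 0.423), VC replicate 1 (0.0532) or VC replicate 2 (0.179), over alternatives from 0.0187 to 0.423. The integrated stress response list had a median of -0.09 (camera adjusted p = 0.0543), which was past the threshold without PBS replicate 2 (0.0344), VC_DZNep replicate 1 (0.0365) or VC_DZNep replicate 2 (0.037), over alternatives from 0.0344 to 0.423. The same camera adjusted p of 0.0543 was found for the endoplasmic reticulum unfolded protein response list (median -0.07), which was past the threshold without VC_DZNep replicate 1 or 2 (0.0454 and 0.047), over alternatives from 0.0454 to 0.411. It was also found for the nuclear genes of the oxidative phosphorylation complexes (median 0.06), which fry called (fry adjusted p = 0.0106).

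The combination was compared with PBS for the joint effect. CLC was 23.7-fold higher, at 652 ± 12.02 against 27 ± 7.07 units, and SETD2 5.45-fold higher. EMILIN2 rose 7.48-fold to 212 ± 16.3 units, the toll-like receptor gene TLR8 5.76-fold and HGF 5.12-fold. The mast cell carboxypeptidase gene CPA3 and the interleukin-33 receptor gene IL1RL1 rose 7.39-fold and 7.08-fold, from 6 ± 0 and 6.5 ± 2.12 units, where 1 rank is a large step. CHAC1 (ENSG00000128965, chr15:40952962-40956519, plus strand) was 19.8-fold lower, at 6 ± 5.66 against 114 ± 16.3 units, again where 1 rank is a large step, and PHGDH (ENSG00000092621, chr1:119648411-119744226, plus strand) was 6.57-fold lower, at 174 ± 34.6 against 1136 ± 112 units.

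Here 1875 genes (19.7%) passed the limma threshold, 906 higher and 969 lower, 420 of them by at least 2-fold. Log2 fold changes were 4.57 ± 0.301 for CLC (adjusted p = 7.38e-06), -4.31 ± 0.492 for CHAC1 (0.000284) and -2.72 ± 0.166 for PHGDH (4.88e-06). Other large increases included SRGN (2.54) and ACTL8 (2.49), and the remaining large decreases were LPAR2 (-2.79), the peptide hormone gene ADM2 (-2.77), ELFN2 (-2.73), the activation antigen gene CD69 (-2.66), IPO5 (-2.56), the nociceptin receptor gene OPRL1 (-2.43), SLC28A3 (-2.36) and TSC22D3 (-2.32). BCL2 fell by 1.39 ± 0.166 (adjusted p = 0.000354), from 296 ± 33.9 to 113 ± 24.0 units. DNMT1 fell by 0.61 (0.00367) and the proliferation marker gene MKI67 rose by 0.72 (0.000568). The count was 1167 without PBS replicate 1, 997 without VC_DZNep replicate 1, 869 without VC_DZNep replicate 2 and 894 with the 4 libraries alone. The OPRL1 call was lost without PBS replicate 1 (limma adjusted p = 0.1) and VC_DZNep replicate 1 (0.119), over alternatives from 0.00356 to 0.119.

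Of the 35 integrated stress response genes, 32 fell over all genes and 34 adjusted over the list alone (mean log2 fold change -1.45, camera adjusted p = 3.74e-32, and adjusted p = 0.00448 with an estimated correlation). PSAT1 fell by 2.27, the mitochondrial phosphoenolpyruvate carboxykinase gene PCK2 by 2.05, ASNS by 1.99 and the glutamyl-prolyl-tRNA synthetase gene EPRS by 1.33 on the log2 scale. Of 31 monocyte and neutrophil maturation genes 15 rose and 6 fell, and adjusted over the list alone 16 rose and 6 fell (median 0.43, camera adjusted p = 0.00186, but adjusted p = 0.122 with an estimated correlation). The shift was not particular to the combination: DZNep alone gave 12 higher and 5 lower (median 0.21, camera adjusted p = 0.0651, fry adjusted p = 0.00242). The combination against VC gave 13 and 4 (median 0.40, camera adjusted p = 0.000668, but adjusted p = 0.122 with an estimated correlation). With the combination against PBS, S100A9 (2.27), the NADPH oxidase gene CYBB (1.82) and the leukotriene synthesis gene ALOX5AP (1.27) rose. The granulocyte colony-stimulating factor receptor gene CSF3R fell by 1.46. Markers of other cell types moved beside these genes: the 4 lymphoid genes had a median of 0.82 with 1 called higher, over all genes and adjusted over the list alone (camera adjusted p = 0.142, fry adjusted p = 0.0134). The called gene was that of the T cell adhesion molecule CD2 (2.00, limma adjusted p = 0.00697, both libraries higher), at 30 ± 11.3 against 6.5 ± 0.707 units. The endothelial and leukocyte adhesion gene PECAM1, the 1 adherent-cell marker measured, was higher as well (0.90, limma adjusted p = 0.012, both libraries higher). The CD2 call was lost without VC_DZNep replicate 2 (0.0868), over alternatives from 0.0018 to 0.0868, and that of PECAM1 without PBS replicate 2 (0.062) and VC_DZNep replicate 1 or 2 (0.0638 and 0.063), over alternatives from 0.00957 to 0.0638. The primary granule list had 7 genes higher and 1 lower, and adjusted over the list alone 8 and 1 (median 0.45, camera adjusted p = 0.00148, but adjusted p = 0.122 with an estimated correlation), the lower gene being that of cathepsin G, CTSG (-1.80).

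Of 24 NRF2 genes 12 rose and 3 fell, and adjusted over the list alone 13 rose and 3 fell (median 0.35, camera adjusted p = 0.00381, but adjusted p = 0.122 with an estimated correlation). The glutathione synthesis gene GCLC rose 2.07-fold, while the transketolase gene TKT fell by 1.08 on the log2 scale and the cystine transporter gene SLC7A11, also on the integrated stress response list, by 1.63. Of 26 lysosome and autophagy genes 8 rose and 1 fell, and adjusted over the list alone 9 rose and 1 fell (median 0.25, camera adjusted p = 0.0046, but adjusted p = 0.16 with an estimated correlation), among them the cathepsin genes CTSA (1.37) and CTSD (1.22) and the membrane gene LAMP1 (0.87). DNA replication genes were lower in 16 of 38 cases and higher in 1, and adjusted over the list alone lower in 17 and higher in 1 (median -0.33, camera adjusted p = 0.00186, but adjusted p = 0.122 with an estimated correlation).

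**Figure D2:**
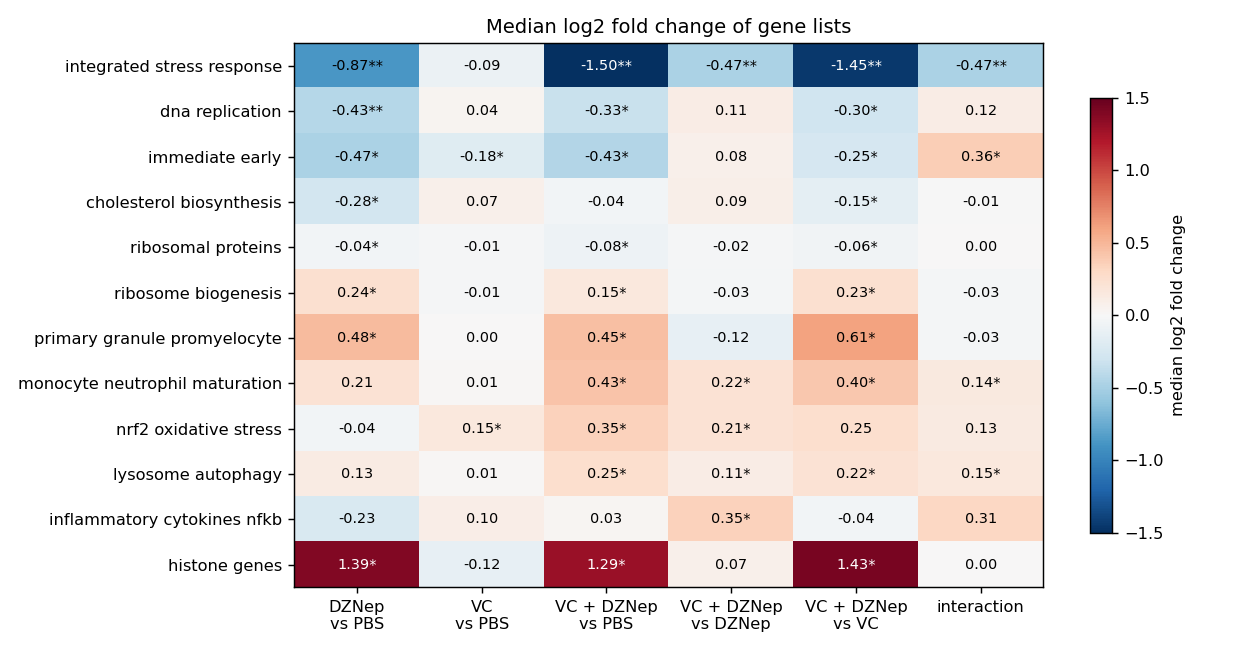
Median log2 fold change of 12 gene lists (vertical axis) in the 6 comparisons (horizontal axis), coloured from blue (lower) to red (higher). Stars mark a camera adjusted p below 0.05 (1 star) that also holds with an estimated correlation (2 stars), and the integrated stress response list stands at -0.87 with DZNep and -0.09 with VC alone.

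The combination was set against DZNep alone to ask what VC added in its presence. BCAT1 (ENSG00000060982, chr12:24810022-24949459, minus strand), the cytosolic branched-chain aminotransferase gene, was 2.04-fold lower, at 502 ± 17.7 against 1026 ± 67.2 units. PSAT1 was 2.12-fold lower, at 154 ± 11.3 against 328 ± 10.6 units, and EPRS (ENSG00000136628, chr1:219968601-220046658, minus strand) was 1.81-fold lower, at 778 ± 8.49 against 1410 ± 46.7 units. BEST1, a chloride channel gene, was 2.16-fold higher, at 903 ± 106 against 417 ± 35.4 units.

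The limma threshold was passed by 64 genes, 25 higher and 39 lower, 15 of them by at least 2-fold. The log2 fold changes were -1.03 ± 0.0851 for BCAT1, -1.09 ± 0.0935 for PSAT1 and -0.86 ± 0.073 for EPRS, each with an adjusted p of 0.000839, and 1.11 ± 0.108 for BEST1 (0.00192). These 4 were past the threshold without any single library, but not without the intensity trend, where their adjusted p were 0.0554, 0.0554, 0.0706 and 0.0706, and PSAT1 and BEST1 also not with the 4 libraries alone (0.0625 each), against lowest values over the alternatives of 0.000105, 0.000105, 0.000123 and 0.000123. The count was 4 without DZNep replicate 1, 16 without DZNep replicate 2, 23 and 20 without VC_DZNep replicate 1 and 2, 32 and 29 without VC replicate 1 and 2, 2 without the intensity trend and 4 with the 4 libraries alone, but 106 under median-of-ratios scaling and 136 with a robust prior.

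The other large decreases were the growth factor gene GAS6 (2.30-fold), the methionyl-tRNA synthetase gene MARS (-1.14), the tubulin gene TUBE1 (-1.06), PHGDH (-1.04), the membrane protein gene ANO7 (-1.02), the amino-acid transporter gene SLC7A5 (-1.01), TSPOAP1 (2.00-fold) and the glycosyltransferase gene OGT (-0.99). The other large increases were the sorbitol dehydrogenase gene SORD (1.34), HGF (2.30-fold), KIAA1551 (2.30-fold), EMILIN2 (2.27-fold), the autophagy receptor gene SQSTM1 (0.89), the receptor gene NOTCH1 (0.80), the nucleoporin gene RANBP2 (0.78), CHI3L1 (0.73) and the helicase-like gene RAD54L2 (0.71). Each of these 17 lost its limma call without DZNep replicate 1, with an adjusted p from 0.0923 for MARS to 0.275 for TSPOAP1. Without DZNep replicate 2, 14 of the 17 lost it, and without VC_DZNep replicate 1 or 2, 13 and 15 did. Without VC replicate 1 or 2, 5 and 7 lost it, and without PBS replicate 1 or 2, 2 each did.

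Of the 35 integrated stress response genes 11 fell over all genes and 21 adjusted over the list alone (median -0.47, camera adjusted p = 1.56e-26, and adjusted p = 0.00657 with an estimated correlation). All 11 had also been called lower with DZNep alone. The NRF2 list had 4 genes higher and 1 lower, and adjusted over the list alone 11 higher and 1 lower (median 0.21, camera adjusted p = 5.26e-07, but adjusted p = 0.0542 with an estimated correlation). Higher were the genes for phosphogluconate dehydrogenase, PGD (0.60), ferritin heavy chain, FTH1 (0.60), SQSTM1, and thioredoxin reductase, TXNRD1 (0.68). Those 4 calls were lost without DZNep replicate 1 (limma adjusted p = 0.147, 0.0923, 0.203 and 0.11), DZNep replicate 2 (0.0718, 0.134, 0.0827 and 0.216), VC_DZNep replicate 1 (0.0647, 0.0965, 0.0727 and 0.0723) or VC_DZNep replicate 2 (0.0807, 0.105, 0.207 and 0.245), and that of TXNRD1 without VC replicate 1 or 2 (0.072 and 0.072).

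Further lists were shifted up by camera with the preset correlation but not with an estimated one. Fry called them too, with an adjusted p of 0.0056 for the maturation list and 0.0418 for DNA methylation enzymes and dioxygenases. For the inflammatory and the lysosome lists the fry adjusted p was 0.0122 each. The monocyte and neutrophil maturation list had 0 genes past the limma threshold over all genes, and 10 higher and 1 lower adjusted over the list alone (median 0.22, camera adjusted p = 0.000207, but adjusted p = 0.0936 with an estimated correlation). Beside this list, the megakaryocyte gene ITGA2B was lower (-0.72 ± 0.112, limma adjusted p = 0.0194, both libraries lower), at 404 ± 13.4 against 669 ± 69.3 units. That call was lost without DZNep replicate 1 or 2 (0.197 and 0.0764), VC replicate 1 or 2 (0.0514 and 0.0517) and VC_DZNep replicate 1 or 2 (0.0945 and 0.182), over alternatives from 0.00106 to 0.197. The adherent-cell marker PECAM1 was not called over all genes (0.52, limma adjusted p = 0.3, both libraries higher) but was higher adjusted over its list alone, where it is the 1 gene measured. The 4 lymphoid genes had 0 past the threshold over all genes and 1 higher adjusted over the list alone (median 0.11, camera adjusted p = 0.662, fry adjusted p = 0.538).

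The inflammatory cytokine and NF-kB list had 0 of 16 past the limma threshold over all genes and 4 higher adjusted over the list alone (median 0.35, camera adjusted p = 0.000207, but adjusted p = 0.0936 with an estimated correlation). The lysosome list had 2 higher over all genes and 6 adjusted over the list alone (median 0.11, camera adjusted p = 0.00135, but adjusted p = 0.157 with an estimated correlation). The list of DNA methylation enzymes and dioxygenases had 0 of 31 past it either over all genes or adjusted over the list alone (median 0.15, camera adjusted p = 0.0142, but adjusted p = 0.157 with an estimated correlation), a call lost without DZNep replicate 2 (camera adjusted p = 0.0529) and VC_DZNep replicate 1 (0.158), over alternatives from 0.00511 to 0.158. Over all genes 1280 had an unadjusted p under 0.05 in this comparison. BCL2 was not called (-0.77 ± 0.166, limma adjusted p = 0.0698), nor was EZH2 (0.17, 0.714) or DNMT1 (0.18, 0.493).

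**Figure D3:**
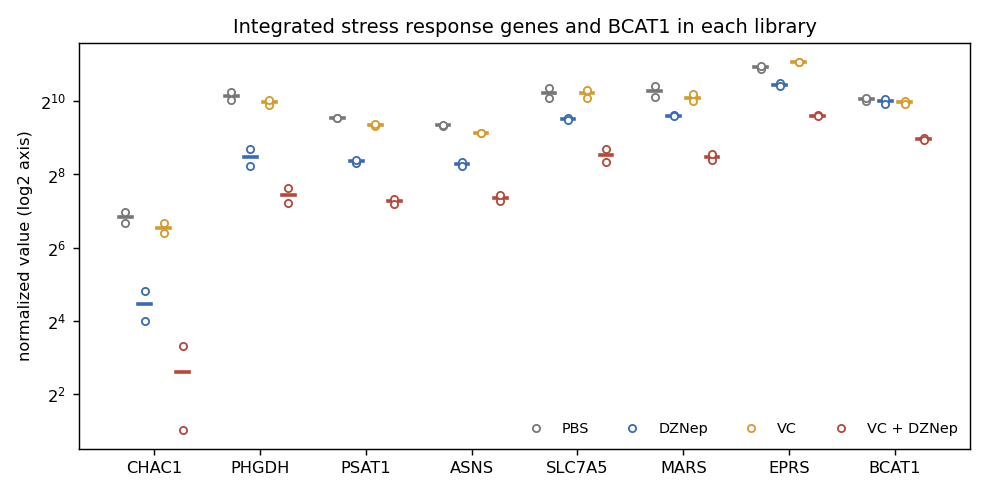
Normalized values (log2 axis) of 7 integrated stress response genes and BCAT1. Open circles are the 2 libraries of each group and bars their arithmetic mean. EPRS stood at 1962 units with PBS, 1410 with DZNep, 2168 with VC and 778 with both.

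The effect of DZNep in the presence of VC was asked by comparing the combination with VC alone. CLC was 31.3-fold higher and EMILIN2 7.98-fold higher, while CHAC1 was 16.3-fold, ADM2 8.06-fold, IPO5 5.91-fold and PHGDH 5.84-fold lower. SETD2 (5.64-fold higher) and CD69 (4.35-fold lower) complete the named genes with CPA3 (17.2-fold) and IL1RL1 (11.4-fold), which were at 2 ± 0 and 4 ± 2.83 units with VC. The lowest value in the table is 2, at which CPA3 stood in both VC libraries and CHAC1 in 1 library of the combination, so these fitted folds of value + 1 are imprecise. The limma threshold was passed by 1429 genes (15%), 655 higher and 774 lower, 320 of them by at least 2-fold, with an adjusted p of 5.81e-06 for CLC and 0.00058 for CHAC1. The count was 501 and 587 without VC replicate 1 and 2, 736 and 575 without VC_DZNep replicate 1 and 2, and 928 without the intensity trend.

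Of the integrated stress response genes 33 fell over all genes and 34 adjusted over the list alone (median -1.45, camera adjusted p = 5.56e-34, and adjusted p = 0.00401 with an estimated correlation). Genes of the primary granule and promyelocyte list were higher in 9 of 14 cases and lower in 1, over all genes and adjusted over the list alone (median 0.61, camera adjusted p = 7.75e-05, but adjusted p = 0.122 with an estimated correlation). Markers of other cell types were higher beside them. The 4 lymphoid genes were all positive with 1 called higher, over all genes and adjusted over the list alone (median 0.41, camera adjusted p = 0.288, fry adjusted p = 0.0451). The called gene was CD2 (2.00 ± 0.403, limma adjusted p = 0.0086, both libraries higher), at 30 ± 11.3 against 6.5 ± 0.707 units. PECAM1 was higher too (0.78 ± 0.202, limma adjusted p = 0.0273, both libraries higher), at 55.5 ± 0.707 against 32 ± 2.83 units. The CD2 call was lost without VC replicate 2 (0.0605) and VC_DZNep replicate 2 (0.104), over alternatives from 0.00223 to 0.104. That of PECAM1 was lost without VC replicate 1 or 2 (0.0936 and 0.157) and VC_DZNep replicate 1 or 2 (0.107 and 0.112), over alternatives from 0.0213 to 0.157.

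The fold changes of DZNep without and with VC come from separate libraries and could be compared directly. Across the 9513 genes, which are not independent replicates, Pearson's r was 0.696 and Spearman's rho 0.637, and 72.8% of genes had the same sign. Both comparisons called 322 genes higher, with 42.1 expected if the calls were independent, and 396 lower, with 51.3 expected, CLC, SETD2, CHAC1 and IPO5 among them. Both comparisons use the same variance per gene, pooled over all groups, which favours calls of the same genes, so these expected counts may be too low. The count called in opposite directions was 0. The VC effects without and with DZNep had an r of 0.127 and a rho of 0.12 across genes, with 53.8% of the same sign, and without PBS replicate 1 that r was 0.0538. DZNep and the combination share the PBS libraries, and their changes had an r of 0.808 where sharing alone gave 0.5 in simulations.

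**Figure D4:**
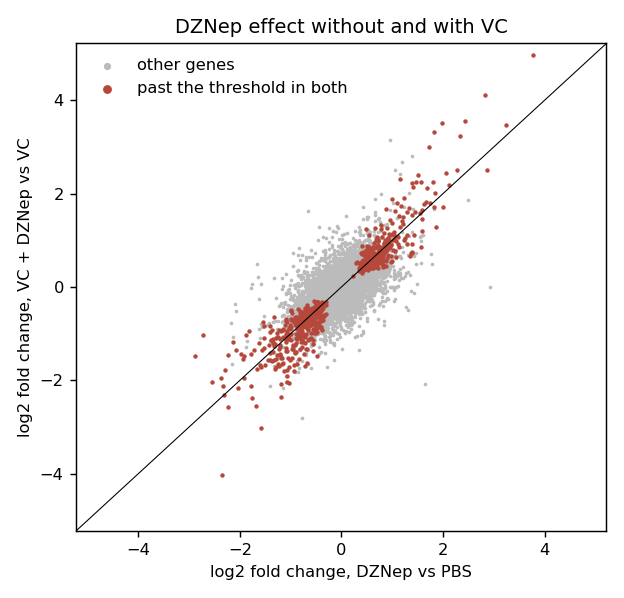
Log2 fold change of each gene for DZNep against PBS (horizontal axis) and for the combination against VC (vertical axis), with the line of equality. Red points are genes past the limma threshold in both comparisons, 322 higher and 396 lower, and grey points are all others.

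Whether the VC effect differed with DZNep was tested by the interaction. EPRS and BCAT1 passed the limma threshold, both lower than the separate effects would give. For EPRS the interaction was -1.001 ± 0.103 on the log2 scale (adjusted p = 0.0141), with means of 1962 ± 83.4 units (PBS), 1410 ± 46.7 (DZNep), 2168 ± 0 (VC) and 778 ± 8.49 (both). For BCAT1 it was -0.95 ± 0.12 (adjusted p = 0.0492), with 1066 ± 47.4, 1026 ± 67.2, 1006 ± 37.5 and 502 ± 17.7 units. The next smallest p belonged to PSAT1 (-0.89, adjusted p = 0.108), the RNA helicase gene DDX3X (0.77, 0.108) and MARS (-0.96, 0.199), which did not pass, and 740 genes had an unadjusted p under 0.05. Of the 35 integrated stress response genes, 1 passed over all genes and 13 were lower adjusted over the list alone (median -0.47, camera adjusted p = 7.09e-19, and adjusted p = 0.0129 with an estimated correlation). The EPRS call was lost without PBS replicate 1 (limma adjusted p = 0.0844), DZNep replicate 1 or 2 (0.159 and 0.0948) and VC replicate 1 or 2 (0.192 and 0.193), over alternatives from 0.00646 to 0.357. The BCAT1 call was lost without any one of the 8 libraries (PBS 0.126 and 0.102, DZNep 0.503 and 0.148, VC 0.297 and 0.314, VC_DZNep 0.0761 and 0.108, replicates 1 and 2 in turn), over alternatives from 0.0199 to 0.503.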

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

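Of the tests below, the matched random lists and the comparison of replicate spread were chosen after the result was seen, and the label for the correlation with GC content was tightened for sampling error after it was seen.

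The deeper fall of the integrated stress response list with both drugs (median interaction -0.47, past the threshold in 11 of 11 alternatives) is the pattern most worth a follow-up. Of its 35 genes 32 had a negative interaction and 3 a positive one, but the sizes were uneven. PSAT1 gave -0.89, SLC7A5 -0.98 and MARS -0.96. ATF4 itself gave -0.05 ± 0.114 (SE), DDIT3 -0.16, TRIB3 -0.22, ATF3 -0.27 and PPP1R15A 0.03, none of them called. The 2.5th percentile of 10000 random lists matched on GC content and exon length was -0.112 and the lowest was -0.224, which argued against a bias from either. A single library that stands apart was argued against by a highest median of -0.418 without 1 library. The submitters' ranking within deciles of gene span stays open: lists matched on span and mean value gave -0.0892, but the ranking gives each decile the same values in each library and so centres such lists near 0 whatever its effect. A lower activity of ATF4 with both drugs is a biological explanation that was not tested.

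VC gave 64 calls in the presence of DZNep and 0 without it. A threshold effect on equal changes was tested by choosing genes in 1 replicate and measuring them in the other, which gave medians of 0.688 with and 0.106 without DZNep, a ratio of 0.154 (0.102 and 0.23 in the 2 choices, bootstrap interval over genes, not libraries, 0.075 to 0.235). The choice divided each change by a spread fitted to all 8 libraries, which favoured genes whose replicates agree. The measuring libraries were thus not separate from the choice, the ratio may be too low, and a threshold effect is not excluded. Replicate spread without DZNep had a ratio of 0.972 to that with it. This cannot decide whether spread parted the calls, because the fit pools 1 variance per gene over all groups. Both comparisons therefore had the same median SE, 0.168. Of the 64 genes, 47 (73.4%) had the same sign with VC alone, with a median signed change of 0.08 against 0.80 with DZNep. The genes were chosen by their change with DZNep, which inflates the 0.80 and fixes part of the gap in advance. TFRC, CFL1 and CHI3L1, which had the smallest p with VC alone, are among the 64. They rose alike without and with DZNep, by 0.80 and 0.69, 0.64 and 0.69, and 0.71 and 0.73. A hypothesis is that VC acts in the same direction on most of these genes and on some of them more strongly with DZNep, which more cultures could test.

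Large changes of long-transcript genes with DZNep were expected as a technical pattern, and the largest changes did not show it. Of the 10 largest increases 6 were in the shortest decile by exon length and 1 in the longest, and of the 10 largest decreases 2 and 1. Of the 105 called increases of at least 2-fold, the shortest decile held 27 and the longest 13. CLC, SRGN, HIST1H4I, RNASE2, ACTL8 and S100A9 lie in the shortest decile, so a tilt toward short transcripts stays open. Over all calls the longest decile had 80 higher and 69 lower, and the shortest 78 and 50, so the long-transcript pattern is not excluded. Spearman's rho of the DZNep fold change was -0.0971 with GC content and -0.0426 with exon length across genes. This leaves a small composition bias open, and rho with gene span was -0.00679. The latter bound, although met, decides nothing, because ranking within span deciles fixes that rho near 0, so the span ranking stays open too.

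The interaction of EPRS was -1.001 and that of BCAT1 -0.95, with calls that depended on the libraries left out. The median interaction of the monocyte and neutrophil maturation list was 0.14 (camera adjusted p = 0.0483, but adjusted p = 0.217 with an estimated correlation), a call lost without PBS replicate 1 or 2 (0.104 and 0.0534), DZNep replicate 1 or 2 (0.0994 and 0.0615), VC replicate 1 (0.0979) or VC_DZNep replicate 2 (0.177), over alternatives from 0.0238 to 0.177. That of the DNA methylation and dioxygenase list was 0.17 (camera adjusted p = 0.0483, but adjusted p = 0.217 with an estimated correlation), lost without PBS replicate 1 or 2 (0.104 and 0.0753), DZNep replicate 1 or 2 (0.118 and 0.0615), VC replicate 1 (0.103) or VC_DZNep replicate 1 (0.191), over alternatives from 0.0296 to 0.191. That of the lysosome list was 0.15 (camera adjusted p = 0.0483, but adjusted p = 0.217 with an estimated correlation), lost without PBS replicate 1 (0.136), DZNep replicate 2 (0.0991), VC replicate 1 (0.0979) or VC_DZNep replicate 2 (0.114), over alternatives from 0.0283 to 0.136. That of the immediate early list was 0.36 (camera adjusted p = 0.0483, but adjusted p = 0.217 with an estimated correlation), lost without PBS replicate 1 (0.281), DZNep replicate 1 (0.195), VC replicate 1 or 2 (0.0632 and 0.0811) or VC_DZNep replicate 1 or 2 (0.087 and 0.114), over alternatives from 0.0241 to 0.281.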

How the results depend on the processing

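The restriction to means from 20 to 2000 and the removal of GC and exon-length trends were chosen after the result was seen. The cause of the moves below was not tested. With 2 libraries per group and moderated variances, counts depend on the prior and on each library. Directions seldom turned, but this says little. Many alternatives leave a fold change as it was, and direction was read only where the main fit or the alternative called the result.

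For DZNep against PBS the count of 1242 became 739 with no trend, 454 with only the 4 libraries compared, 251 with an absolute log2 fold change of at least 1, and 439 to 1030 without 1 library. For VC against PBS it became 1 with median-of-ratios size factors, 1 with a mean from 20 to 2000, 1 with the GC and exon length trend removed, and 0 to 1 without 1 library. For the combination against PBS 1875 became 894 with only the 4 libraries compared, 420 at an absolute log2 fold change of at least 1, and 869 to 1633 without 1 library. For the combination against DZNep 64 became 106 with median-of-ratios size factors, 2 with no trend, 136 with trend and robust, 4 with only the 4 libraries compared, 15 at an absolute log2 fold change of at least 1, 140 with a mean from 20 to 2000, 166 with the GC and exon length trend removed, and 4 to 70 without 1 library. For the combination against VC 1429 became 928 with no trend, 320 at an absolute log2 fold change of at least 1, and 501 to 1532 without 1 library. The interaction count of 2 became 1 with a mean of at least 50, 0 with no trend, 0 with trend and robust, 1 with vooma weights, 1 at an absolute log2 fold change of at least 1, 8 with the GC and exon length trend removed, and 0 to 2 without 1 library. With a replicate block the 6 counts were 1367, 0, 1944, 95, 1508 and 3.

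With an estimated correlation the numbers of lists called were 2, 0, 1, 1, 1 and 1 in the same order, against 8, 2, 11, 6, 11 and 5. Without 1 library they were 6 to 8, 1 to 4, 9 to 11, 5 to 7, 9 to 11 and 1 to 4. The r of the DZNep effects was 0.762 with a mean of at least 50 and 0.616 to 0.674 without 1 library, and that of the VC effects 0.0538 to 0.15. With the GC and exon length trend removed, 3 mitochondrially encoded genes turned direction: MT-ATP8 gave -0.14, MT-ND3 -0.0858 and MT-ND4L -0.24 for DZNep against PBS, -0.30, -0.10 and -0.31 for the combination against PBS, and MT-ATP8 -0.39 and MT-ND4L -0.35 for the combination against VC. The median of the mitochondrially encoded list, 0.14, 0.11 and 0.11 in these comparisons and not called, became -0.17, -0.20 and -0.26 and was called (camera adjusted p = 0.0183, 0.0116 and 0.00183). Of the named genes called, 32 of 107, 48 of 119, 0 of 29, 34 of 107 and 0 of 2 were called under every setting, leaving out VC against PBS.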

Other observations

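No test below was chosen after the result was seen.

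TFRC rose from 448 ± 21.9 units with PBS to 873 ± 63.6 with DZNep and 1410 ± 46.7 with both (SD, n = 2), with log2 fold changes of 0.96 (limma adjusted p = 0.000381) and 1.65 (4.74e-06), both libraries higher in each. The ferritinophagy receptor gene NCOA4 rose by 0.89 with DZNep. The angiogenic growth factor gene VEGFA fell by 1.66 with DZNep, from 724 ± 24.0 to 229 ± 24.0 units, and the NF-kB subunit gene NFKB2 fell by 1.41. The haem and iron list as a whole had 3 genes higher over all genes, and 3 higher and 2 lower adjusted over the list alone (median -0.12, camera adjusted p = 0.836, fry adjusted p = 0.682), and the hypoxia list 3 higher and 4 lower, and 7 higher and 4 lower adjusted over the list alone (median 0.09 and mean -0.06, camera adjusted p = 0.867, fry adjusted p = 0.127).

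Camera, which compares a list with all other genes, did not call the following lists with DZNep, while the rotation test fry called 3 of them. Of 25 polycomb genes 2 rose and 2 fell, over all genes and adjusted over the list alone (median -0.14, camera adjusted p = 0.139, fry adjusted p = 0.0171). Of 34 mitosis genes 2 rose and 2 fell, and 3 and 3 adjusted over the list alone (median -0.07, camera adjusted p = 0.738, fry adjusted p = 0.797), with CENPF up and the mitotic kinase gene AURKB lower by 1.04. Of 35 genes of the BCL2 family and caspases 1 rose and 5 fell, and 4 and 7 adjusted over the list alone (median 0.00 and mean -0.08, camera adjusted p = 0.489, fry adjusted p = 0.0877), and of 19 p53 targets 3 fell, also adjusted over the list alone (median -0.01, camera adjusted p = 0.489, fry adjusted p = 0.0122). Markers of lymphoid cells, 4 genes, had a median of 0.83 (camera adjusted p = 0.139, fry adjusted p = 0.0258). Over the 30 lists fry called 18 for DZNep against PBS, 2 for VC against PBS, 19 for the combination against PBS, 9 for it against DZNep, 19 for it against VC and 2 for the interaction.

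In the combination against PBS, camera called 5 further lists with the preset correlation but not with an estimated one. Fry called each of them, with an adjusted p from 0.00249 for the immediate early list to 0.0301 for ribosome biogenesis. Of 8 histone genes 5 rose and 1 fell, over all genes and adjusted over the list alone (median 1.29, camera adjusted p = 0.00744, but adjusted p = 0.35 with an estimated correlation). Of 78 ribosomal protein genes 13 fell, and 11 adjusted over the list alone (median -0.08, camera adjusted p = 0.00392, but adjusted p = 0.16 with an estimated correlation), and of 13 immediate early genes 6 fell, also adjusted over the list alone (median -0.43, camera adjusted p = 0.00186, but adjusted p = 0.122 with an estimated correlation). Of 40 ribosome biogenesis genes 8 rose and 3 fell, over all genes and adjusted over the list alone (median 0.15, camera adjusted p = 0.0221, but adjusted p = 0.288 with an estimated correlation), a call lost without PBS replicate 1 (0.0986) and VC_DZNep replicate 1 (0.151), over alternatives from 0.00844 to 0.151. Of 15 heat shock genes 3 rose and 1 fell, over all genes and adjusted over the list alone (median 0.21, camera adjusted p = 0.0365, but adjusted p = 0.288 with an estimated correlation), a call lost without PBS replicate 1 (0.116) and VC_DZNep replicate 2 (0.0571), over alternatives from 0.0296 to 0.116.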
